A study of Mus musculus with 12 samples.

How the data were processed

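The 12 samples are total RNA from the liver and the esophagus of 6 mice, with 3 TG and 3 CTR mice and 1 array each per organ, and the series design calls the 3 mice of a genotype biological replicates. The mice had a mixed 129Sv/C57BL6 background, and their water held 7.5% sucrose with the doxycycline. Per the labels' protocols, esophagus RNA was made with a kit for fibrous tissue and liver RNA with Trizol and a column, so organ and extraction cannot be told apart, RNA integrity numbers ran from 7.3 to 9.5, and 1 µg of RNA was labelled with Cy3 per array.

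Each array has a deposited scanner file with spot intensity values on a linear scale. Per the file headers these were made by Agilent Feature Extraction 10.7.1.1 from a 4x44K mouse array, design 14868, which subtracted the background within each array and did not scale the arrays to each other. The authors also deposited a table of log2 values for the same 12 arrays, and limma is named without a version per the submitters' processing notes. The values show that this table is quantile-normalized and not centred, with every column median at 7.27; how its background was treated is not given in the sources used here. Each of its columns correlated at 0.999 or higher with normexp and quantile values of its own array, and 0 of its columns lacked a sample.

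Control spots and the 1311 spots marked as outliers by the scanner software on the 12 arrays were left out, spots of one probe were averaged, and no spot was saturated. Of the probes, 23374 were named by matching their accessions to the RefSeq gene table of GRCm38.p6, giving 16535 genes, and the 17800 others were kept as units under their own identifiers. The array design was annotated on mm8, so no coordinates are given. Values were log2 of the processed signal minus the 75th percentile of that array, which ran from 8.91 to 10.1 on the log2 scale. A gene was tested in an organ where its probe was well above background on all 3 arrays of at least 1 of the 2 groups, and the brightest probe stood for a gene with several. All 12 arrays entered one limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with 4 groups, no block and 8 residual degrees of freedom, and the contrasts were TG minus CTR in esophagus, in liver, and the first minus the second. Tests were two-sided, with Benjamini-Hochberg adjustment at 0.05 over the genes tested in a contrast. Tables were handled with data.table (1.17.8) and jsonlite (2.0.0), and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

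Before the data were examined, the tests, the rule for naming genes and 24 gene lists were fixed: mitosis, DNA replication and S phase, p53 targets and CDK inhibitors, basal, suprabasal and inflamed keratinocytes, pluripotency, hepatocyte genes, lipid synthesis, fasting response, xenobiotic and bile acid metabolism, circadian clock, interferon response, immediate early and heat shock genes, skeletal muscle, smooth muscle, fibroblasts and matrix, leukocytes, endothelium, adipocytes, cholangiocytes, stomach with airway and gland, nerve and glia, and red blood cells. The series title, which names mitosis, was known when they were written. The list of red blood cells had under 5 tested members, and 23 were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 23 lists. Fry asks whether a list's genes move on balance one way and does not compare them with other genes. With the preset correlation 7 lists were called in esophagus, 2 in liver and 6 for the difference; with an estimated correlation 0, 0 and 0; with fry 1, 0 and 0. The values of each list on each array are medians over its members. Members matched to the array numbered 49 of 53 for mitosis, 32 of 36 for S phase and 21 of 22 for basal keratinocytes, and Mki67 was among those without a matched probe.

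The rule for naming genes has 4 parts. Nanog, Col1a1, Aurka, Plk1, Ccnb1, Bub1 and Mki67 are named always. In each organ the 10 largest changes per direction that pass are named, or, where none passes, the 3 smallest p per direction as values that did not pass. For each list described, up to 4 tested members with the smallest p are named. For the difference between organs the 5 largest per direction that pass are named, or the 3 smallest p per direction. Genes outside the rule, such as Rag1, Isg15 and Oas1a, were chosen after their values were seen, as were 7 further marker lists for heart, thymus, airway, fat, liver transcripts and both phases of the clock. They were built after the pattern was seen, so no p is given for them, while the levels of their members serve in the closing tests.

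The procedure was tested on simulated data with known changes. Over the 23212 esophagus genes it recovered 30% of 50 genes changed by a log2 value of 1, 68% of those changed by 2, 92% by 3 and 92% by 4, with 5 unchanged genes among 146 calls. Over the 21250 liver genes it recovered 38%, 82%, 90% and 98%, with 8 unchanged genes among 162 calls. A mitosis list shifted by 1 was called in both organs with 0 other lists. The simulated genes varied independently of each other, so this does not test the preset correlation on members that move together. In the real esophagus the estimated correlation was 0.36 for the mitosis list and 0.46 for the S phase list.

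The labels give a liver and an esophagus array of each replicate one animal number, so these pair by animal across organs. The correlation of paired deviations from the group means ran from -0.04 to 0.16 in TG and from -0.05 to 0.07 in CTR, and 1 of 3 TG and 0 of 3 CTR esophagi correlated best with the liver of their own number. The animal was tested as a random block for the difference between organs. All mice are labelled male, and Ddx3y, Eif2s3y, Kdm5d and Uty were well above background and Xist was not on all 12 arrays. No 2 arrays were near identical, the highest correlation being 0.988.

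Alternatives tried were normexp with quantile normalization, quantile normalization over all arrays and within each organ, no filter on dim probes, a filter on all 6 arrays of an organ, every probe on its own, the authors' deposited log2 table, each organ fitted alone, trend and robust variance, array weights, the replicate number as a block, the slide as a fixed or a random block and within slides, and leaving out each of the 12 arrays. Normexp used an offset of 50 and the median spot signal, since the files read here hold no mean signal column. The 12 arrays lay on 5 slides, and the scan batches were the slides. Within an organ only esophagi TG1 and CTR2, and livers TG3 and CTR2, shared a slide, so slide and genotype are largely confounded. Added after seeing the data were fits without esophagus TG1 and TG2, where the lone TG array is assumed to vary like the other groups, without liver TG2 and CTR1, without liver TG3 and CTR3, with a common floor under dim values, with livers TG1 and CTR1 or esophagi TG1 and CTR1 exchanged, and, for the difference between organs, over genes tested in both organs.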

Results

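RNA from the liver and the esophagus of 6 male mice was measured on 12 arrays, 1 array per organ and mouse. In 3 mice (TG) doxycycline was given to switch on a Nanog transgene at the Col1a1 locus through the rtTA activator at Rosa26, and 3 mice (CTR) carried the activator alone. All 6 drank doxycycline at 0.2 mg/ml for 48 h at about 8 months of age. Nanog is a transcription factor of pluripotent embryonic cells, and the series title puts the question of how it acts on the mitotic genes of adult layered epithelia, of which the esophagus is one. Between 56.4% and 81.8% of the probes were well above background on an array, and the number of arrays limits the precision. Arrays of one group correlated at 0.951 to 0.988 across genes and arrays of different organs at 0.635 to 0.664, so that every array matched the organ of its label. The one Nanog probe (NM_028016) was not well above background on any of the 12 arrays, with normalized log2 signals of -8.10 ± 0.21 (SD, n = 3) in TG and -8.26 ± 0.20 (SD, n = 3) in CTR esophagus, so the arrays did not show induction of the transgene. The probe's place in the mRNA was not analysed here. Weak or absent induction therefore cannot be told apart from a probe that misses the transgene's RNA.

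In the TG esophagus the genes of mitosis were called higher as a group with the preset correlation of camera alone, not with an estimated correlation (adjusted p = 0.132) or with fry (adjusted p = 0.123). Of the 49 measured members of the mitosis list, 48 had a higher mean in TG than in CTR, and the median difference was 0.95 on the log2 scale (camera in limma, preset correlation, adjusted p = 5.85e-29). Ccnb1 (NM_172301), the cyclin that drives entry into mitosis with Cdk1, differed by 1.69 (SE 0.31), and Kif20a (NM_009004), a kinesin of cell division, by 1.61 (SE 0.35). Cenpe (NM_173762), a kinesin that moves chromosomes to the spindle equator, differed by 1.50 (SE 0.31) and Cdca3 (NM_013538), a trigger of mitotic entry, by 1.38 (SE 0.28). The mitotic kinases Plk1 (NM_011121), Bub1 (NM_009772) and Aurka (NM_011497) differed by 1.42 (SE 0.33), 1.24 (SE 0.65) and 0.72 (SE 0.23), and with dim values set to a common floor Bub1 was at 0.49. No member passed over all genes tested, and 13 passed adjusted over the list alone; the lowest of their limma adjusted p over all genes, for Ccnb1, was 0.572.

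The mitosis list stood at 0.99 ± 0.45 (SD, n = 3) in TG and at -0.05 ± 0.22 (SD, n = 3) in CTR esophagus, as the median over its members relative to the control mean. Esophagus TG1 stood at 1.44, TG2 at 0.99 and TG3 at 0.53, all above the highest control at 0.17. In 35 of the 49 members all 3 TG values lay above all 3 CTR values, where chance gives 5% in one direction for a single gene. The members come from the same arrays and had an estimated correlation of 0.36, so they are not independent and the 35 cannot be weighed against 5%. For such a separation of 3 against 3 arrays an exact permutation test gives p = 0.1, its smallest possible value. With the slide as a fixed block the median was 1.42, with the slide as a random block 1.02, and within the slide that held esophagus TG1 and CTR2 it was 1.21. TG1, TG2 and TG3 lay on slides 3, 4 and 5, and CTR1, CTR2 and CTR3 on slides 2, 3 and 1. The fixed block thus takes slide effects in part from the liver arrays, as if both organs shared them. A slide effect on the mitosis list is therefore not excluded. The control esophagi also carried transcripts of other organs, described further on. The heart transcript Nppa was lower on all 3 TG arrays, and fat and airway transcripts were lower on TG1 and TG3. As a list, heart genes on TG2 (-1.02) and TG3 (-1.22) lay near CTR2 (-0.93), with TG1 at -2.05 and CTR1 high at 1.08. In clock genes TG1 and TG2 stood apart. With TG3 as the only TG array the mitosis median was 0.53. Clock genes of liver and esophagus did not match in the animals of TG1 and CTR1, and with the labels of esophagi TG1 and CTR1 exchanged, a setting chosen after seeing the data, the mitosis median was -0.0037 (adjusted p = 0.721).

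**Figure D1:**
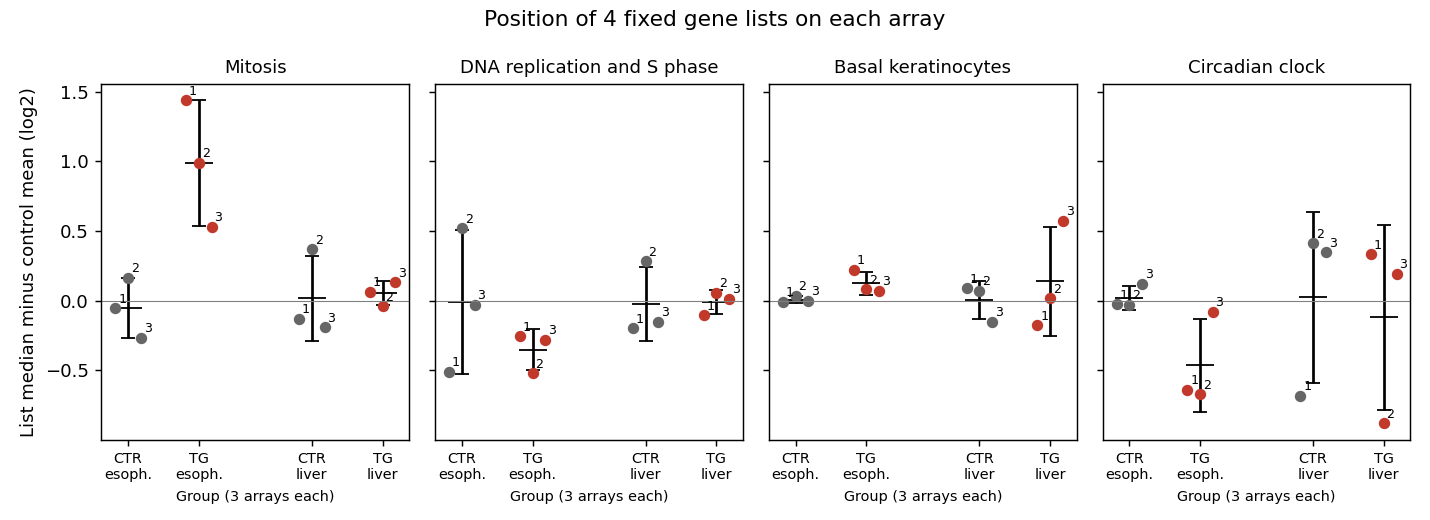
Position of 4 gene lists on each array, as the median over list members relative to the control mean (log2), with points numbered by replicate and bars showing the group mean ± SD (n = 3). In the mitosis panel the 3 TG esophagi lie between 0.53 and 1.44 and the 3 control esophagi between -0.27 and 0.17.

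The lists for the layers of the epithelium itself were not called. Basal keratinocyte genes, which mark the layer that holds the dividing cells, had a median difference of 0.11 with 13 of 21 members higher in TG (camera adjusted p = 0.690). Itgb4 and Col17a1, which anchor basal cells to the matrix below, differed by 0.29 (SE 0.19) and 0.39 (SE 0.30), and the stem cell factor Sox2 by 0.37 (SE 0.31). Suprabasal and cornifying genes had a median of 0.05 with 14 of 24 members higher (adjusted p = 0.951), among them Sprr1a, a precursor of the cornified envelope, at 1.38 (SE 0.45) and the keratin Krt10 at -1.25 (SE 0.59). Krt10 ran from -1.68 to -0.49 with single arrays left out and from -3.29 to 0.17 over the other settings. The 2 genes with the smallest p among those higher in TG were Sprr2f (NM_011472), another envelope precursor, at 6.25 (SE 0.88), and Krtap3-2 (NM_025720), a hair keratin-associated protein, at 3.74 (SE 0.44). Krtap3-2 stood between -0.65 and -0.21 on the TG and between -4.62 and -3.36 on the CTR arrays. Neither passed, with limma adjusted p = 0.255 and 0.139, though Sprr2f did with the slide as a fixed block (7.38, adjusted p = 0.00767). Krtap3-2 passed in 6 of 17 settings other than leaving out single arrays. These were quantile normalization over 12 arrays (3.62, adjusted p = 0.00179) and within each organ, normexp and the authors' table (2.66, adjusted p = 3.98e-05). The others were array weights and the common floor (3.44, adjusted p = 0.000208). Except with array weights it then also passed for the difference between organs, though its probe was not well above background on any liver array. The pluripotency list had a median of -0.07 and a mean of 0.03 with 7 of 16 members higher (adjusted p = 0.971).

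DNA replication and S phase genes moved the other way from mitosis genes, with 5 of 32 members higher in TG and a median of -0.36 (camera adjusted p = 7.99e-07). With an estimated correlation the adjusted p = 0.598. Mcm3 and Mcm4, subunits of the replicative helicase, differed by -1.24 (SE 0.43) and -0.70 (SE 0.29), Dut, which keeps uracil out of DNA, by -0.64 (SE 0.22), and E2f1, a transcription factor of S phase genes, by -0.73 (SE 0.26). No member passed, either over all genes or adjusted over the list alone. The control arrays spanned -0.51 to 0.52, and the TG arrays at -0.25, -0.52 and -0.28 lay near the lower part of that span. Without esophagus CTR2 the median was -0.16 and the call was lost (adjusted p = 0.425).

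Lists of transcripts typical of other organs were called lower in the TG than in the control esophagus with the preset correlation. Hepatocyte genes fell, with 1 of 21 members higher in TG and a median of -0.46 (camera adjusted p = 1.10e-12; adjusted p = 0.0784 with an estimated correlation and 0.0481 with fry). The list stood at -0.56, -0.64 and -0.76 on TG1, TG2 and TG3 and at -0.30, 0.19 and 0.20 on CTR1, CTR2 and CTR3. Alb (NM_009654), serum albumin, differed by -3.04 (SE 0.47), F2 (NM_010168), prothrombin, by -1.25 (SE 0.20), and the plasma proteins Apoh and Ahsg by -1.27 (SE 0.26) and -0.87 (SE 0.22); 6 members passed adjusted over the list alone and 0 over all genes. Alb was well above background on 2 of the 3 TG arrays and Apoh on 1, and with the common floor Alb was at -1.98, F2 at -0.73 and Apoh at -0.079. Adipocyte genes fell with 0 of 10 members higher and a median of -1.37 (adjusted p = 1.14e-06; 0.266 with an estimated correlation). The shift lay in 2 of the 3 TG mice, with TG1 at -2.06 and TG3 at -2.00, while TG2 at 0.049 lay among the controls at 0.64, 0.055 and -0.45. In that list the fat hormone Lep differed by -4.28 (SE 0.78), with 1 of 3 TG arrays well above background, so that the size depends on the background treatment: it was -1.80 with a common floor (not passing), -1.62 with normexp (adjusted p = 0.0178) and -1.49 in the authors' table (adjusted p = 0.0444). The heat-producing Ucp1 of brown fat differed by -4.91 (SE 1.81), and the lipid proteins Plin1 and Fabp4 by -1.85 (SE 0.77) and -1.04 (SE 0.44). The list of stomach, airway, gland, thyroid and pancreas genes fell with 2 of 12 members higher and a median of -0.33, its mean being -1.85 (adjusted p = 3.78e-05; 0.232 with an estimated correlation). The groups overlapped, with TG1, TG2 and TG3 at -0.94, -0.64 and -0.33 and the controls at 0.46, -0.59 and -0.64, so that CTR1 alone stood high. Its airway genes had the smallest p, with Bpifa1 at -7.60 (SE 2.20), Scgb1a1 of club cells at -3.29 (SE 0.96), Scgb3a1 at -4.51 (SE 1.23) and Foxj1, the regulator of motile cilia, at -4.36 (SE 1.18). Foxj1 was well above background on 1 of 3 TG arrays and was at -2.80 with the common floor and -2.17 with normexp.

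Red blood cell genes had 4 tested members, too few for the list test. Hbb-bt and Hba-a1, chains of hemoglobin, differed by -1.21 (SE 0.35) and -0.97 (SE 0.42), neither passing over all genes, and the list stood at -1.12, -0.87 and -0.76 on TG1, TG2 and TG3 and at 0.36, 0.14 and -0.50 on CTR1, CTR2 and CTR3.

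The transcripts of other organs differed between single mice. Nppa (NM_008725), the atrial natriuretic peptide of the heart, had the smallest p among genes lower in TG, with -6.49 (SE 0.93), and stood at 5.41, 0.48 and 3.97 on CTR1, CTR2 and CTR3 and between -3.28 and -3.10 on the TG arrays. It did not pass (limma adjusted p = 0.255) but did without CTR2 (-7.90, adjusted p = 0.000102). Bpifa1 stood between 3.93 and 7.09 on the control arrays and at 4.35 on TG2, against -5.29 on TG1 and -5.78 on TG3, and Ucp1 was likewise high on TG2 (2.97) and low on TG1 (-5.29) and TG3 (-4.58). Without TG2, 7 genes passed over all genes tested, all lower in TG, among them Bpifa1 (-10.90) and Ucp1 (-7.55). Without CTR1, Alb was among 3 genes that passed (-3.70, adjusted p = 0.00480). Lists for heart, airway and fat, chosen after these genes had been seen, had medians of -1.57, -3.29 and -1.73, and their p values are not given since the lists were built from the pattern.

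**Figure D2:**
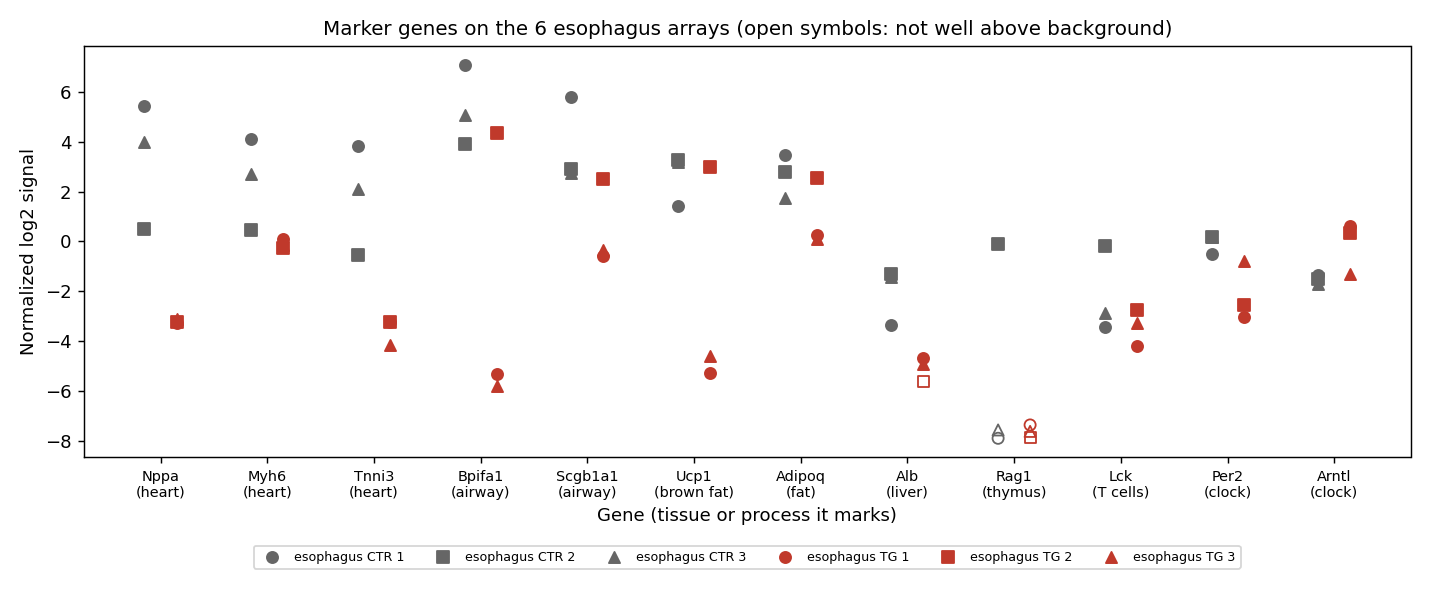
Normalized log2 signal of 12 marker genes on the 6 esophagus arrays, with one symbol shape per replicate number and open symbols where the probe was not well above background. Nppa lies at 0.48 or higher on the 3 control arrays and at -3.10 or lower on the 3 TG arrays, while Bpifa1 and Ucp1 on TG2 lie near the controls.

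Clock and leukocyte genes also fell as lists in the TG esophagus. The circadian clock list had 5 of 20 members higher in TG and a median of -0.46 (camera adjusted p = 0.0386; 0.654 with an estimated correlation). Per2, a repressor within the clock, differed by -2.07 (SE 0.89), the clock output factor Hlf by -1.24 (SE 0.39), and Arntl, the clock activator, by 1.40 (SE 0.84). The shift lay in 2 of the mice, since Per2 stood at -3.01 on TG1 and -2.55 on TG2 but at -0.80 on TG3, against -0.50 to 0.17 on the controls. The leukocyte list had 3 of 20 members higher and a median of -0.29 (adjusted p = 0.0168; 0.654 with an estimated correlation), with the mast cell proteases Cpa3 and Mcpt4 at -1.03 (SE 0.43) and -1.14 (SE 0.52) and the T cell kinase Lck at -1.25 (SE 0.72). Esophagus TG1 alone stood low at -1.26, and without it the leukocyte median was 0.027 (adjusted p = 0.955); without CTR1 or CTR2 the call was lost as well (adjusted p = 0.116 and 0.175). Among the esophagi CTR2 alone carried the thymus gene Rag1 above background, at -0.11, as did the liver of that animal among the livers, at -3.40, and esophagus CTR2 had the highest Lck, at -0.18. The clock call was lost without esophagus TG1, CTR1 or CTR2 in turn (adjusted p = 0.0863, 0.0880 and 0.212), without liver TG1 (adjusted p = 0.0569), and with every probe tested on its own (median -0.32, adjusted p = 0.104). With TG3 as the only TG array the clock median was -0.077. Over all alternatives other than leaving out single arrays it ran from -0.64 to -0.019.

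Over single genes of the esophagus, limma called 0 of 23212 changed at an adjusted p under 0.05, with 902 at an unadjusted p under 0.05 (452 higher and 450 lower in TG) and a smallest adjusted p = 0.139. Chance alone would on average give more than 902 at that limit. Col1a1 (NM_007742), whose locus holds the transgene, differed by -0.10 (SE 0.42), with 0.19 and 0.20 from its other probes. The other 16 lists tested in the esophagus were not called.

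In the liver a group of endothelial genes was lower in TG, and the mitosis list was not called. Of 11 endothelial members 1 was higher, and the median was -0.31 (camera adjusted p = 0.000702; 0.713 with an estimated correlation). Tie1 and Tek, receptors of endothelial cells, differed by -0.63 (SE 0.32) and -0.50 (SE 0.33), Stab2, a scavenger receptor of the liver sinusoids, by -0.40 (SE 0.27), and Eng by -0.31 (SE 0.22). The shift came from liver TG1, at -1.04 against -0.11 to 0.14 on the 5 other livers, and without it the median was 0.0034. With the slide as a fixed block it was -0.083, with the call lost (adjusted p = 0.0862), and within the slide that held liver TG3 and CTR2 it was 0.17.

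The mitosis list had 18 of 29 tested members higher in TG liver and a median of 0.12, while camera, which compares with all other genes, gave the direction as down (adjusted p = 0.537). The median over all 21250 genes tested in liver was 0.13, so the list did not stand out from it, and with quantile normalization, where that median was 0.02, the list stood at -0.075, as it did at -0.065 without liver CTR3. Nuf2 and Pttg1, needed for chromosome segregation, differed by 0.97 (SE 0.42) and 0.32 (SE 0.22), with Nuf2 at 0.72 under the common floor and well above background on 2 of 3 control arrays. Cdca8 differed by -0.27 (SE 0.25), Aurka by -0.34 (SE 0.23), Plk1 by 0.12 (SE 0.33) and Ccnb1 by 0.16 (SE 0.31); with quantile normalization Plk1 was at -0.067 and Ccnb1 at -0.76. Bub1 was not well above background on any liver array. No member's TG and CTR values were apart without overlap.

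Xenobiotic and bile acid genes were called as lower in TG liver with a median of -0.075 and 13 of 28 members higher (camera adjusted p = 0.0165; 0.713 with an estimated correlation). Cyp27a1, an enzyme of bile acid synthesis, differed by -0.84 (SE 0.28), the drug-inducible Cyp2b10 and its relative Cyp2b9 by -1.55 (SE 0.67) and -1.78 (SE 0.89), and Sult1e1, which inactivates estrogen, by -0.81 (SE 0.45). The list separated livers TG2 (-0.62) and CTR1 (-0.72) from the other 4 (0.05 to 0.47). The same 2 livers stood apart in the clock, with Per2 at -1.77 and -1.64 against 0.63 to 1.23 on the other 4. Without liver TG2 the median was 0.14 and without CTR2 it was 0.10, with adjusted p = 0.269 and 0.423, without CTR3 it was -0.045 (adjusted p = 0.269), and with quantile normalization it was -0.12 (adjusted p = 0.263). The pluripotency list was not called in liver (median 0.30, 10 of 14 members higher, adjusted p = 0.266). In it Tbx3, at 1.09 (SE 0.23), and Pou5f1, the partner of Nanog in embryonic stem cells, at 1.45 (SE 0.37), passed adjusted over the list alone but not over all genes. Of 5 equal groups of the liver genes tested, ranked by signal, the dimmest had a median of 0.46, or 0.20 without liver TG3, and Pou5f1 was well above background on 2 of the 3 control arrays.

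Over single genes of the liver, limma called 0 of 21250 changed, with 1618 at an unadjusted p under 0.05 (1186 higher and 432 lower in TG) and a smallest adjusted p = 0.651. The smallest p among genes higher in TG were those of Zbtb1 (NM_178744) at 0.87 (SE 0.15), Tbc1d24 (NM_173186) at 0.97 (SE 0.17) and Ccdc85a (NM_181577) at 2.47 (SE 0.47). Among genes lower in TG they were those of Abca3 (NM_013855), a lipid transporter, at -1.14 (SE 0.20), Nudt18 (NM_153136) at -1.07 (SE 0.20) and the stress-induced Gadd45g (NM_011817) at -1.62 (SE 0.31). Ccdc85a was well above background on 1 of 3 control livers and Tbc1d24 on 2, and with the common floor they were at 1.17 and 0.28. Another probe of Zbtb1 gave 0.37, and Zbtb1 passed with the common floor (adjusted p = 0.0484). Other probes of Abca3 gave -1.51 and 0.25 and another probe of Nudt18 gave 0.35. Col1a1 differed by 0.65 (SE 0.42), with 1.03 and 0.84 from its other probes. Without liver TG1 4 genes passed and without liver TG2 7, among them Gadd45g (-1.99, adjusted p = 0.0458). The other 21 lists tested in the liver were not called.

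The response of mitosis genes was called as different between the organs with the preset correlation of camera alone. The esophagus difference minus the liver difference had a median of 0.83 over 49 members, 43 of them positive (camera adjusted p = 8.62e-17, against 0.575 with an estimated correlation and 0.477 with fry). Of these members 20 were not well above background on all 3 arrays of either liver group and so had no tested liver response, and over the 29 measured in both organs the median was 1.04 with 26 positive (adjusted p = 9.51e-18; 0.408 with an estimated correlation). With TG3 as the only TG esophagus the median over the 49 was 0.38, and with esophagi TG1 and CTR1 exchanged it was -0.10 (adjusted p = 0.485). Another split, with animals 121, 122 and 131 on one side in both organs, gave 1.07 (camera, preset correlation, adjusted p = 1.67e-10). Cenpe, Ccnb1, Ccnb2, a second mitotic cyclin, and Aurka differed between the organs by 1.51 (SE 0.43), 1.53 (SE 0.44), 1.56 (SE 0.47) and 1.06 (SE 0.33), and Plk1 by 1.30 (SE 0.47). Adipocyte genes had a median of -2.02 (adjusted p = 0.00263), stomach, airway, gland, thyroid and pancreas genes -1.10 (adjusted p = 0.00263), hepatocyte genes -0.29 (adjusted p = 0.00711) and fibroblast and extracellular matrix genes -0.43 (adjusted p = 0.0259). Endothelial genes had a median of 0.21 (adjusted p = 0.00602), and with an estimated correlation these 5 lists had adjusted p from 0.575 to 0.819. In the matrix list Thy1, a fibroblast surface protein, differed by -0.70 (SE 0.29) and the collagen Col1a2 by -0.56 (SE 0.25). That list had a median of -0.09 in esophagus and 0.39 in liver, and stomach and airway genes had 0.72 in liver. The median over all genes tested for the difference was -0.14. Dim liver genes shifted upward as a whole, the dimmest of 5 equal groups by 0.46, or 0.20 without liver TG3. Over genes measured in both organs the adipocyte and the stomach and airway lists lost their calls (-1.02 and -0.59; adjusted p = 0.0713 and 0.0589). Single arrays decided several of these calls: adipocyte genes were at -0.90 without liver CTR1 (adjusted p = 0.0869) and endothelial genes at 0.15 without liver TG1 (adjusted p = 0.302), 0.11 without esophagus TG2 (adjusted p = 0.0531) and 0.15 without esophagus CTR2 (adjusted p = 0.115). Hepatocyte genes lost the call without liver TG1, TG2 or CTR1 or esophagus CTR3 (-0.27, -0.36, -0.26 and -0.25; adjusted p from 0.0667 to 0.0931). Matrix genes lost it without liver TG1, TG2 or CTR3 or esophagus TG1, CTR1 or CTR3 (-0.48, -0.52, -0.35, -0.37, -0.36 and -0.40; adjusted p from 0.0524 to 0.176). The adipocyte, airway and hepatocyte values include the transcripts of other organs in the control esophagi described above.

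Limma called 0 of 24444 genes for the difference, with 1189 at an unadjusted p under 0.05 (348 positive and 841 negative) and a smallest adjusted p = 0.953. Chance alone would on average give slightly more than 1189 at that limit. The smallest p were those of Mchr1 (NM_145132), a receptor for melanin-concentrating hormone, at 3.90 (SE 0.67) from 2 TG arrays per organ, Aar2 (NM_026661) at 0.99 (SE 0.22) and Nudt18 at 1.23 (SE 0.28) among positive values. Among negative values they were Nppa at -6.70 (SE 1.32), Zbtb1 at -1.08 (SE 0.21) and Tnni3 (NM_009406), a troponin of heart muscle, at -6.39 (SE 1.28). Another probe of Aar2 gave -0.22 in esophagus and 0.69 in liver, where the tested probe gave 0.25 and -0.75, and another probe of Nudt18 gave -0.50 and 0.35, where the tested probe gave 0.16 and -1.07.

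**Figure D3:**
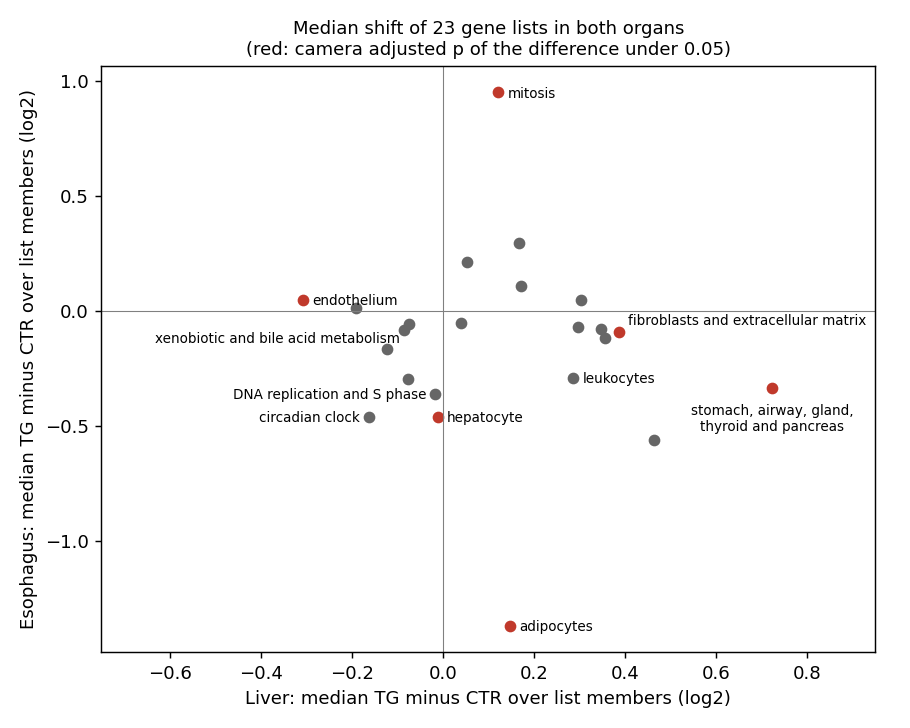
Median TG minus CTR difference (log2) of the members of 23 gene lists in esophagus (vertical axis) against liver (horizontal axis), with lists in red where the difference between organs had a camera adjusted p under 0.05. The mitosis list lies at 0.95 in esophagus and 0.12 in liver, which becomes -0.075 in liver with quantile normalization.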

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

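All tests weighing explanations here were chosen only after the results were seen, but not the lists or the test of the difference between organs. 6 lists stood out because the response in esophagus differed from that in liver by a test of the difference itself, with the preset correlation: mitosis at a median log2 difference of 0.83, adipocytes at -2.02, stomach, airway, gland, thyroid and pancreas at -1.10, hepatocyte genes at -0.29, fibroblasts and matrix at -0.43 and endothelium at 0.21. With an estimated correlation their adjusted p ran from 0.575 to 0.819. Single arrays ended the calls of all but mitosis and the stomach and airway list: without liver TG1 hepatocyte genes (-0.27), matrix (-0.48) and endothelium (0.15) lost theirs, and without liver CTR1 adipocytes (-0.90). Over genes tested in both organs the adipocyte list (-1.02) and the stomach and airway list (-0.59) lost theirs too, and mitosis was at 1.04.

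Mitosis genes were higher in TG esophagus by 0.95. Dilution of the epithelium by tissue attached to the control esophagi would move basal keratinocyte genes about as much, and their median difference was 0.11 with an SD over members of 0.23, which argues against dilution as the whole cause. A different time of day at collection may contribute, since clock genes of esophagus TG1 and TG2 stood apart; TG3, with clock genes near the controls, kept mitosis genes at 0.53, but it is 1 array and leaves this open. Of the 10 splits of the 6 esophagi 1, the real one, gave a mitosis median as large (0.95 against 0.89 in the highest other), and for the difference between organs 3 did (0.83 against 1.07), and 10 splits are too few for a share under 0.05. Both highest other splits were also called by camera with the preset correlation (adjusted p = 3.50e-21 and 1.67e-10). Further esophagus splits were called by the same test, at medians of 0.60, 0.47, 0.31, 0.52 and -0.22. Their adjusted p by camera were 3.96e-14, 1.02e-08, 0.0359, 3.56e-05 and 0.0372. The preset call by itself therefore does not set the real split apart. An effect of the transgene, the difference the design names, stays open, as the Nanog probe did not show its induction. An exchange of esophagi TG1 and CTR1, with which the mitosis median is -0.0037, stays open as well.

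Transcripts of other organs were higher on average in control esophagi, though fat and airway genes on TG2 lay near the controls. Heart tissue attached to the esophagus stays open: 10 of 14 cardiac genes, without the 3 whose values led to the list, were highest in CTR1, but so were 6 of 8 airway and 6 of 7 fat genes, so the peak is not particular to heart genes, and esophageal muscle also expresses some of them, such as Actc1. Liver RNA carried over stays open: the median gap between other liver transcripts and the level Alb predicts was -0.68 over 10 transcripts, 7 of them below it, and the gaps ran from -1.63 to 4.42. Their SD of 1.98 and scaled median deviation of 0.54 lead to different verdicts, the highest gaps may be the esophagus's own expression, and several transcripts lay near the floor. No biological explanation was tested.

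Clock genes in liver and esophagus stood in different states in animals 121 and 131, which are TG1 and CTR1. An exchange of livers TG1 and CTR1 might explain this. It gave 64 probes that followed the animal in both organs against 53 as labelled. At stricter limits it gave 17 against 10 and 7 against 2. The lead was under a factor of 2 at the first and second limits. At these limits in turn 2, 1 and 2 of 720 pairings of the animals gave as many as the exchange. As many as the labels were given by 5, 21 and 193 pairings. A second form of the check did not single the exchange out, and an exchange of esophagi TG1 and CTR1 gives the same pairing, with a mitosis median of -0.0037 in esophagus and -0.10 for the difference in place of 0.95 and 0.83; the labels were kept, and the mitosis result rests on them. With the livers exchanged 115 liver genes were called against 0 as labelled (limma, 1618 as labelled at an unadjusted p under 0.05), among them the lipid synthesis genes Acly (-2.01) and Elovl6 (-2.67), chosen after their values were seen. A split that calls this many genes points to a structure of the samples, and time of day, feeding or a label exchange cannot be told apart here.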

How the results depend on the processing

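Settings without 2 named arrays, with a common floor under dim values, over genes tested in both organs or with livers or esophagi exchanged were chosen after seeing the data. In esophagus 0 genes were called by limma (902 at an unadjusted p under 0.05), against 2 with normexp and quantile normalization, 1 with quantile over 12 arrays or within each organ, 2 with the authors' table, 1 each with each organ alone, array weights, the slide as fixed block, or without TG1 and TG2, and 3 with the common floor. In liver 0 were called (1618 unadjusted), against 8 without TG2 and CTR1, 3 without TG3 and CTR3, 14 with the floor and 115 with livers TG1 and CTR1 exchanged. For the difference 0 were called (1189 unadjusted), against 1 with normexp, quantile over 12 arrays or within each organ, the authors' table or the floor, and 2 without liver TG3 and CTR3. Leaving out single arrays gave 0 to 7 in esophagus, 0 to 7 in liver and 0 to 1 for the difference. The cause was not tested for any of these, apart from what leaving out arrays shows by construction.

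The estimated correlation and fry ended the calls, at unchanged medians, of mitosis (0.95), S phase (-0.36), adipocytes (-1.37), stomach and airway (-0.33) in esophagus, endothelium in liver (-0.31) and the mitosis difference (0.83); the estimated correlation alone ended that of hepatocyte genes (-0.46). Both tests allow for correlation between members, which the preset does not estimate. Within slide 3 the S phase median was -0.82 and that of stomach and airway -0.91. Liver endothelium was -0.083 with the slide as fixed block, 0.17 within slide 2 and 0.37 with livers exchanged, and its difference was -0.28 with livers exchanged. With esophagi TG1 and CTR1 exchanged the mitosis list lost its call and its direction (-0.0037; -0.10 for the difference), and leukocytes (0.41), adipocytes (0.43) and stomach and airway (0.43) changed direction in esophagus. The liver mitosis median of 0.12 was -0.052 with normexp, -0.075 with quantile over 12 arrays, -0.077 within each organ, -0.053 with the authors' table, -0.0018 with the slide as fixed block, -0.25 without TG3 and CTR3, -0.11 with livers exchanged and -0.24 within slide 2.

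Leaving out single arrays, the mitosis median ran from 0.77 to 1.21 in esophagus, from 0.51 to 1.24 for the difference and from -0.065 to 0.25 in liver. In esophagus S phase ran from -0.59 to -0.16, hepatocyte genes from -0.74 to -0.45, adipocytes from -2.03 to -1.01, stomach and airway from -0.64 to -0.29 and leukocytes from -0.56 to 0.027. In liver xenobiotic genes ran from -0.47 to 0.14 (0.10 without CTR2) and endothelium from -0.53 to 0.0034. For the difference adipocytes ran from -3.05 to -0.90, stomach and airway from -1.72 to -0.80 and hepatocyte genes from -0.51 to -0.25. Also for the difference, matrix genes ran from -0.58 to -0.35 and endothelium from 0.11 to 0.57.

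The replicate numbers of TG and CTR share only a number. With the replicate block, fixed within each organ, 0 genes were called in either organ and the mitosis list stayed called in esophagus (0.95). For the single genes named, 3010 of 3110 results over all settings kept direction and side of the threshold, 20 passed where they had not, and 80 changed sign or, within a slide, moved beyond the replicate spread. Of these 52 changed sign, in 31 results, 0 of them with an adjusted p under 0.05 by limma, among them Plk1, Ccnb1 and Stab2 in liver and Col1a1 in esophagus. The count of 3010 was partly fixed in advance, since leaving out an array of one organ largely keeps the difference in the other. The named genes seldom passed in any setting, so the side of the threshold could seldom change. Signal over background limits dim genes in liver: liver TG3 had a negative-control signal of 28.6 against 15.9 to 19.5 on the other arrays, and the dimmest of 5 equal groups of liver genes shifted by 0.46, or 0.20 without it.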

Other observations

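The counts over splits of the samples here were chosen only after the results were seen. Esophagus TG3 stood high in interferon response genes, with a list position of 0.90 against the control mean, Isg15 at 2.71 and Oas1a at 1.29, while the list was not called in esophagus (median 0.21). Rag1, a gene of developing lymphocytes, was above background only on esophagus CTR2 at -0.11 and liver CTR2 at -3.40, which come from the same animal. Esophagus TG2 had the highest signal of Sftpc, a surfactant protein of lung alveoli, at 6.18. These genes were chosen after their values were seen.

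Medians of lists that were not called in esophagus were -0.05 for p53 targets and CDK inhibitors, 0.30 for inflamed keratinocytes, -0.16 for lipid synthesis, 0.01 for fasting, -0.06 for xenobiotic metabolism, -0.08 for immediate early genes, -0.08 for skeletal and -0.30 for smooth muscle, -0.09 for fibroblasts, 0.05 for endothelium, -0.11 for cholangiocytes and -0.56 for nerve and glia. In liver they were -0.02 for S phase, 0.04 for p53 targets and CDK inhibitors, 0.17 for basal, 0.30 for suprabasal and 0.17 for inflamed keratinocytes, -0.01 for hepatocyte genes, -0.12 for lipid synthesis, -0.19 for fasting, -0.16 for the clock, 0.05 for interferon and -0.09 for immediate early genes. Also in liver they were 0.35 for skeletal and -0.08 for smooth muscle, 0.39 for fibroblasts, 0.29 for leukocytes, 0.15 for adipocytes, 0.36 for cholangiocytes, 0.72 for stomach and airway and 0.46 for nerve and glia.

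Each comparison has 10 splits of the samples into 3 against 3, too few for a share under 0.05. In esophagus 10 of 10 splits gave at least the 0 genes called by limma (902 at an unadjusted p under 0.05), the highest other being 0, and 2 called at least 7 lists, the highest other being 8. In liver 10 gave at least the 0 genes called (1618 unadjusted), the highest other being 115, which points to a structure of the samples, 6 a mitosis median as large as 0.12, the highest other being 0.50, and 9 at least 2 lists, the highest other being 8. For the difference 10 gave at least the 0 genes called (1189 unadjusted), the highest other being 1, and 7 at least 6 lists, the highest other being 10.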
